A study of Mus musculus with 6 samples.

How the data were processed

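The series holds 6 single-channel Illumina bead arrays of subcutaneous adipose tissue from male FVB mice, 3 from wild type and 3 from mitoNEET transgenic tissue. Per the labels' protocols, tissue was snap frozen, total RNA was extracted and cleaned, and biotin-labelled cRNA was hybridised. The deposited values are probe intensities on a linear scale. The software that normalized them is not given in the sources used here. The deposited intensities were found to be quantile-normalized, since the sorted values of the 6 arrays differed by at most 0.157, and not background-subtracted, since the lowest value was 32.4. Quantile normalization gives all arrays the same distribution, so a shift shared by most genes cannot be seen in these values. A table of scanner output was not used: its 24 columns of per-array values are named by chip and position, which match no sample's label. For that reason detection p-values and chip positions were not used here, and whether chips differed between the groups is not known.

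The plan made before the data were examined was to apply neqc to scanner signals and to filter on detection p-values. Without scanner columns that could be assigned, log2 of the deposited intensities was analysed instead, and the filter was replaced by a threshold on intensity. These replacements were chosen after the values had been inspected and before any group was compared. The background level was taken as the mode of all log2 values, 47.8 in intensity, and the threshold as the mode plus about 1.6 times the spread of the values below it, 55.6 in intensity. A probe was kept when it exceeded the threshold on at least 3 of 6 arrays, which kept 22037 of 45281 probes (48.7%). Because a background level remains in the values, folds of dim genes are understated.

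Probes were named through the platform annotation, which can be old. It gives 1 gene for 34885 probes, several for 18 and none for 10378; probes with several or none were tested but not named. Entrez identifiers of 34807 probes were found in a gene table of GRCm38.p6, and no symbol needed changing. No coordinates are printed because no build is stated for the array. Each gene was represented by its kept probe with the highest mean. Fits that left out arrays made this choice again on the remaining arrays, so the probe of a gene could differ there. Of 4690 genes with more than 1 kept probe, 808 had some probes past the threshold and some not, and 4 had probes past it in both directions.

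The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, its moderated test) with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. On simulated data with 200 changed features among the 14962, the fit called 46.3% of features changed by 0.5 on the log2 scale, 83.6% of those changed by 1 and 97.0% of those changed by 2. Of 158 calls 7 were unchanged features. The simulated noise was drawn independently for each feature. Variation that many features of an array share was therefore absent, and these rates need not hold for the real arrays. Before the data were examined, 37 lists of pathways, complexes and cell type markers were fixed, and 35 with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01. Of these, 12 passed, 6 higher and 6 lower. With the correlation estimated from the data 0 passed after adjustment and 1 had an unadjusted p under 0.05, and with limma's fry 0 passed and 12 had an unadjusted p under 0.05. Camera compares a list with the other genes, whereas fry asks whether its genes move on balance in a direction. The score of a list on an array is the mean deviation of its members from their 6-array means.

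Genes were named by a rule fixed before the data were examined: Cisd1, Cisd2 and Cisd3; the 10 largest rises and 10 largest falls past the threshold without overlap between groups; up to 4 members of smallest p from each list described; and the key genes Adipoq, Lep, Pparg, Cd36, Ucp1, Ppargc1a, Cpt1a, Tfrc, Slc25a37, Vegfa, Kdr, Col6a3, Tnf, Saa3 and Adgre1 wherever measured. Col6a3 and Cisd3 were not analysed here. Genes named outside the rule are said to be so. Alternatives covered an added offset, the filter, the choice of probe, the moderated test, array weights, a replicate block, the threshold and each array left out in turn. With all probes tested separately, each named gene was given by its probe of smallest p. A discordant probe of larger p could not show in that setting, whose values are counted with the others below. Background subtraction, centring, a covariate built from lymphocyte genes and the joint exclusion of wild type array 2 and transgenic array 1 were added after the data were seen.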

Results

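Gene expression was measured on Illumina bead arrays in subcutaneous adipose tissue of male FVB mice aged 12 weeks. There were 3 arrays from wild type tissue and 3 from tissue of mice carrying a mitoNEET transgene. MitoNEET is an iron-sulfur protein of the outer mitochondrial membrane and is encoded by Cisd1. The comparison asks how tissue expression differed between the genotypes. All 6 arrays had the same distribution of intensities, with medians of 54.8, and about 48.4% of the 45281 probes lay above background on each. After the filter on dim probes, 14962 features were tested, of which 11469 were named genes and 3493 were probes with no single gene listed. Intensities are given as mean ± SD over 3 arrays, and changes as log2 transgenic minus wild type with the standard error of limma's fit. The labels do not state that each array came from a separate animal, so the p-values measure the spread between these samples, and the number of arrays limits the precision.

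The transgene's own product was examined before other genes. The Cisd1 probe (Entrez Gene 52637) read 915 ± 132 (SD, n = 3) in wild type tissue and 1086 ± 23.4 (SD, n = 3) in transgenic tissue, a log2 difference of 0.26 (SE 0.11), or 1.19-fold. All 3 transgenic arrays lay above all 3 wild type arrays, yet limma's adjusted p was 0.163. A two-sided exact permutation test gave p = 0.1, the smallest value that 3 against 3 arrays allow. Whether the transgene carries the sequence this probe reads is not known here, so the value is a weak check of the labels. The Cisd2 probe stayed below the background threshold, and Cisd3 was not analysed here.

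In camera's test with a preset correlation, lists of lymphocyte, thermogenic, cell cycle and inflammatory genes were lower in transgenic tissue, and lists of adipocyte, adipokine and endothelial genes were higher. None of these lists passed with an estimated correlation (adjusted p 0.552 or more) or with fry (0.0779 or more). At an adjusted p under 0.05 in limma's moderated test, 765 features were higher in transgenic tissue (624 named genes) and 1236 were lower (880 named genes), 2001 in all. Falls were also the larger changes: 317 features fell at least 2-fold and 19 rose at least 2-fold. In 5370 of the 14962 features the groups did not overlap, a separation that chance gives in 10% of features. When each array was centred on the median of its kept features, 1117 features were higher and 1086 lower, so that 50.7% of calls were rises, against 38.2% without centring. This centring moved the median log2 change of all features up, from 0.026 to 0.063, so it favours rises. The count rested on particular arrays: without transgenic array 2 no feature passed (3629 had an unadjusted p under 0.05 in limma), without wild type array 2 there were 316, without transgenic array 1 there were 513, and without transgenic array 3 there were 1211. Leaving out both wild type array 2 and transgenic array 1 gave 317, and subtracting a background level gave 345.

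The 10 largest falls included genes of lymphocytes and of lymphoid tissue. H2-M2, a class Ib histocompatibility gene, fell 5.60-fold, from 1518 ± 461 to 298 ± 162 (log2 −2.48, SE 0.41, adjusted p = 0.0155). Fcmr, the Fc receptor for IgM, fell 5.46-fold and Bcl11b, a T cell transcription factor, fell 5.12-fold. The lymphoid chemokines Ccl19, Cxcl13 and Ccl21c changed by −2.35, −2.32 and −2.27. Glycam1, a ligand of L-selectin made by high endothelial venules, went from 2660.5 ± 1038 to 585 ± 329. The T cell surface genes Cd3d and Cd6 and the lymphocyte receptor gene Cd27 changed by −2.33, −2.27 and −2.30. Ccl21c has near-identical copies and the H2-M genes belong to a large family, and binding of their probes to relatives was not examined. Without transgenic array 1 the falls were smaller, at −1.59 for Ccl19, −1.47 for Ccl21c, −1.59 for Cd3d, −1.72 for Bcl11b and −1.71 for Glycam1. Of 6 single exclusions, Ccl19 and Ccl21c lost their calls in 4, Cd3d in 3, Cxcl13 in 1 and the other 6 genes in 2.

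The largest rise was in Comp, a matrix protein of cartilage and tendon, from 109 ± 59.7 to 426 ± 197 (3.95-fold; log2 1.98, SE 0.41, adjusted p = 0.0218). H2-M9 rose 3.38-fold, Cdhr5, a cadherin-related gene, 2.87-fold, and Kcne1l, a potassium channel subunit gene, 2.83-fold. Grin3a (log2 1.30), the sulfate transporter gene Slc13a4 (1.24), the glycine transporter gene Slc6a9 (1.22), the collagen receptor gene Ddr1 (1.21), Il17re (1.15) and Anln (1.13) completed the 10 largest rises. In all 10, wild type array 3 was the highest of the wild type arrays, with Comp at 178 there against 80.1 and 69.9 on wild type arrays 1 and 2. Across the 6 fits that each leave out 1 array, H2-M9, Cdhr5, Grin3a, Slc13a4 and Anln lost their calls in 5, Ddr1 in 4, and Comp, Kcne1l, Slc6a9 and Il17re in 3, and H2-M9 ranged from 1.33 to 2.40.

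**Figure D1:**
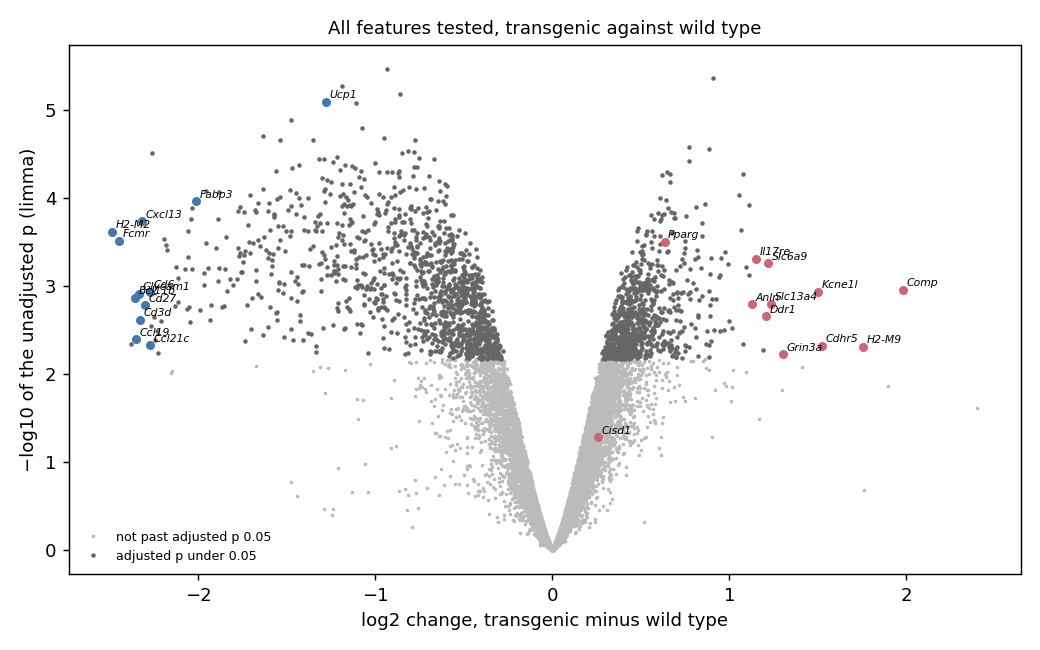
Each point is 1 of the 14962 features, with the log2 change (transgenic minus wild type) on the horizontal axis and −log10 of limma's unadjusted p on the vertical axis; dark points have an adjusted p under 0.05 and coloured points are named genes. Changes beyond 2-fold were mostly falls, 317 against 19 rises, and Cisd1 lay among the features that did not pass at a log2 change of 0.26.

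Both lymphocyte lists were lower in camera's test. Of 17 measured B and plasma cell genes, 16 fell and 1 rose, with a median log2 change of −1.61 (camera adjusted p = 5.02e-11; 16 lower and 1 higher when adjusted over the list alone). Mzb1, a chaperone gene of antibody-secreting cells, fell 3.89-fold (log2 −1.96, SE 0.28, adjusted p = 0.0145), Blk, a B cell kinase gene, fell 3.39-fold, Btla fell 2.43-fold and Vpreb3 fell 2.08-fold. The member that rose was Xbp1 (log2 0.53), which is also expressed widely outside B cells and is named after its value was seen. Of 20 measured T and NK cell genes, 13 fell and 7 did not pass, with a median of −1.28 (camera adjusted p = 1.64e-08; 16 lower when adjusted over the list alone). Il7r, the interleukin-7 receptor gene, fell 3.35-fold, Zap70, a T cell receptor kinase gene, fell 3.28-fold, Thy1 fell 2.10-fold and Prf1, the perforin gene, fell 1.60-fold. Transgenic array 1 had the lowest T and NK cell score (mean log2 deviation −1.23) and wild type array 2 the highest (0.90); without both arrays the medians were −0.74 for T and NK cells and −1.13 for B and plasma cells. With an estimated correlation between genes both lists had an adjusted p = 0.552, and no single gene passed without transgenic array 2 (Mzb1 adjusted p = 0.0522). In the 6 fits with 1 array left out, Xbp1 lost its call in 4, Il7r and Zap70 in 2, and Mzb1, Blk, Btla, Vpreb3, Thy1 and Prf1 in 1.

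Ucp1 and 5 other thermogenic genes were lower in transgenic tissue. Ucp1, the uncoupling protein of brown and beige adipocytes (Entrez Gene 22227), fell 2.43-fold, from 6499.7 ± 547 to 2698 ± 449 (SD, n = 3; log2 −1.28, SE 0.13, adjusted p = 0.0145). Fabp3, a fatty acid binding protein gene, fell 4.04-fold (log2 −2.01, SE 0.30), Acot11, a thioesterase gene, fell 1.97-fold and Cpt1b, a mitochondrial carnitine palmitoyltransferase gene, fell 1.48-fold. Across the list, 6 of 22 measured members fell and 1 rose, with a median of −0.28 (camera adjusted p = 0.00269; also 6 lower and 1 higher when adjusted over the list alone). The other members that fell were Cox7a1 (log2 −0.86) and Letmd1 (−0.56), and the member that rose was Lhx8 (0.53); these 3 are named after their values were seen. Ppargc1a, a coactivator of mitochondrial biogenesis, had a log2 difference of 0.08 (SE 0.11, adjusted p = 0.68). Prdm16 and Cidea, also named afterwards, had log2 differences of −0.01 and 0.26 with adjusted p-values of 0.944 and 0.183. With an estimated correlation the list's adjusted p was 0.552, with an unadjusted p of 0.0257. Wild type array 2, which carried a high level of skeletal muscle genes, also had the highest thermogenic score (0.47); without it Ucp1 changed by −1.23 (SE 0.15, adjusted p = 0.0396) and Cox7a1 by −0.77 (adjusted p = 0.0736). Of 6 single exclusions, Ucp1 lost its call in 1, without transgenic array 2 (log2 −1.13, adjusted p = 0.0522), as did Fabp3 and Acot11, Cpt1b lost its call in 2, and Cox7a1, Letmd1 and Lhx8 in 3.

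**Figure D2:**
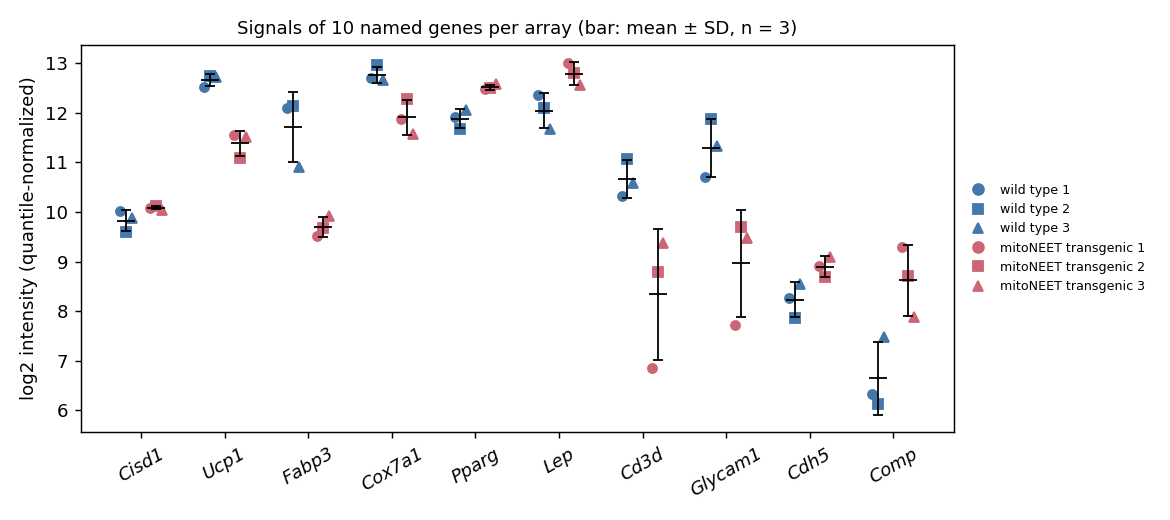
Log2 intensity of 10 named genes on each array, wild type in blue and mitoNEET transgenic in red, with a separate symbol for each replicate number; bars show mean ± SD of 3 arrays. Ucp1, Fabp3, Cox7a1, Cd3d and Glycam1 were lower on all 3 transgenic arrays, and Pparg, Lep, Cdh5 and Comp were higher on all 3.

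Among mature adipocyte genes 8 were higher in transgenic tissue. Pparg, the master regulator of adipocyte differentiation (Entrez Gene 19016), rose 1.55-fold, from 3807 ± 503 to 5878 ± 207 (SD, n = 3; log2 0.63, SE 0.11, adjusted p = 0.0162). Slc2a4, the insulin-responsive glucose transporter gene, rose 1.46-fold, Aqp7, a glycerol channel gene, rose 1.51-fold and Rbp4, the retinol binding protein gene, rose 2.00-fold. Of 23 measured members 8 rose and 15 did not pass, with a median of 0.31 (camera adjusted p = 2.31e-05; 12 higher when adjusted over the list alone). Adipoq, the adiponectin gene, read 12856 ± 1304 against 15609 ± 762, a log2 difference of 0.28 that did not pass (SE 0.10, adjusted p = 0.0907). Cd36 stayed near background, between 48.4 and 62.3 on the 6 arrays, and was not tested. Fabp4, named after its value was seen, is among the measured members but also read near background, between 59.4 and 75.2. Such readings cannot show whether a gene is weakly expressed or its probe reads poorly. The list's adjusted p was 0.552 with an estimated correlation. Among single exclusions the median was lowest, 0.27, without transgenic array 1. With a lymphocyte score as covariate the median was 0.06 (camera adjusted p = 0.331). Across the 6 fits that each leave out 1 array, Pparg lost its call in 1, without transgenic array 2 (adjusted p = 0.0583), and Slc2a4, Aqp7 and Rbp4 in 4.

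Some adipokine genes and genes of fatty acid uptake and triglyceride synthesis rose. Lep, the leptin gene (Entrez Gene 16846), rose 1.68-fold, from 4310 ± 1003 to 7148 ± 1120 (SD, n = 3; log2 0.75, SE 0.18, adjusted p = 0.0339). Nampt rose by 0.59 on the log2 scale and Agt, the angiotensinogen gene, rose 1.31-fold. Of 16 measured adipokine genes 6 rose and 10 did not pass, with a median of 0.33 (camera adjusted p = 0.0148; 9 higher and 1 lower when adjusted over the list alone). Among 26 measured genes of fatty acid uptake and triglyceride synthesis, 4 rose and 1 fell, with a median of 0.17 (camera adjusted p = 0.0289; 5 higher and 1 lower when adjusted over the list alone). Fabp5 rose by 0.57, Gpat3, a glycerol phosphate acyltransferase gene, by 0.56, Aqp7 by 0.59 and Dgat2 by 0.30, the last of these named after its value was seen. Acsl5, an acyl-CoA synthetase gene, was the member that fell (log2 −0.49, SE 0.10, adjusted p = 0.023). With an estimated correlation the adjusted p was 0.552 for adipokines and 0.585 for fatty acid uptake, and with the lymphocyte covariate both calls were lost (camera adjusted p = 0.784 and 0.858). The fatty acid uptake call also ended with the filter on all 6 arrays (camera adjusted p = 0.052). In the 6 fits with 1 array left out, Lep lost its call in 3, Nampt, Fabp5, Aqp7 and Acsl5 in 4, Agt and Gpat3 in 5, and Dgat2 in 6.

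Among endothelial and angiogenesis genes 3 were higher, beside 765 rises and 1236 falls among all 14962 features. Angpt1, a ligand of the Tek receptor, rose 1.61-fold, from 137 ± 8.4 to 222 ± 26.3 (SD, n = 3; log2 0.69, SE 0.11, adjusted p = 0.0145). Cdh5, the vascular endothelial cadherin gene, rose 1.59-fold and Sox17, an endothelial transcription factor gene, rose 1.36-fold. Gpihbp1, which anchors lipoprotein lipase to capillaries, had a log2 difference of 1.09 that did not pass (SE 0.33, adjusted p = 0.0601). Of 27 measured members 3 rose and 24 did not pass, with a median of 0.31 (camera adjusted p = 0.00057, with 1 higher when adjusted over the list alone). The list score was 0.11 on wild type array 3, near the 0.13 to 0.18 of the transgenic arrays. On wild type arrays 1 and 2 it was −0.24 and −0.35. The median ran from 0.21 without wild type array 2 to 0.44 without wild type array 3. Vegfa, the angiogenic growth factor gene, rose by 0.59 (SE 0.15, adjusted p = 0.041) on the log2 scale, whereas Kdr, which encodes its receptor, was measured near background at 62.4 ± 2.88 and 64.1 ± 6.65. The list's adjusted p was 0.65 with an estimated correlation, and with the lymphocyte covariate its camera adjusted p was 0.115. Of 6 single exclusions, Cdh5 and Sox17 lost their calls in 5, Vegfa in 4 and Angpt1 in 1.

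A few iron and antioxidant genes rose, beside 765 rises and 1236 falls among all 14962 features. Counting both directions, the share called was close to that of all features for iron and below it for oxidative stress. Of 35 measured genes of iron handling and iron-sulfur cluster assembly, 4 rose and 1 fell, with a median of 0.11 (camera adjusted p = 0.0419; also 4 higher and 1 lower when adjusted over the list alone). Heph, a ferroxidase gene, rose by 0.59 (SE 0.14, adjusted p = 0.0328) on the log2 scale, Hfe, which encodes a regulator of iron uptake, 1.48-fold, and Fbxl5, an iron-sensing ubiquitin ligase subunit gene, 1.32-fold. Trf, the transferrin gene, also rose (log2 0.68) and is named after its value was seen. Slc25a37, the gene of the mitochondrial iron importer mitoferrin, fell from 212 ± 10.1 to 170.5 ± 7.66 (log2 −0.31, SE 0.08, adjusted p = 0.0438). Tfrc, the transferrin receptor gene, had a log2 difference of 0.41 (SE 0.17, adjusted p = 0.138). Of 33 measured oxidative stress genes, 3 rose, with a median of 0.17 (camera adjusted p = 0.0289; also 3 higher when adjusted over the list alone). Gpx7 and Gpx8, of the glutathione peroxidase family, rose by 0.54 and 0.42, and Nqo1, a quinone reductase gene, by 0.48. Both lists had an adjusted p = 0.585 with an estimated correlation. The list calls were lost with the filter on all 6 arrays (camera adjusted p = 0.081 for iron and 0.0505 for oxidative stress), without wild type array 2 (0.0868 and 0.0531) and without transgenic array 1 (0.0528 and 0.0713), and with the lymphocyte covariate both medians were below 0, at −0.02 and −0.03; with 1 array left out the medians ran from 0.07 to 0.16 for iron and from 0.09 to 0.23 for oxidative stress. Across the 6 fits that each leave out 1 array, Slc25a37 lost its call in all 6, Trf and Gpx8 in 5, Heph, Hfe and Fbxl5 in 4, Gpx7 in 3 and Nqo1 in 2.

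Among inflammatory genes 5 were lower, and among cell cycle genes 9. Icam1 and Vcam1, adhesion molecules for leukocytes, fell 1.80-fold and 1.75-fold, with Icam1 going from 585 ± 49.5 to 325 ± 33.1 (SD, n = 3; log2 −0.85, SE 0.11, adjusted p = 0.0145). The chemokine Ccl5 fell 4.54-fold, Cxcl13 4.98-fold, and Tnf 1.67-fold (log2 −0.74, SE 0.14, adjusted p = 0.0182). Of 30 measured inflammatory genes these 5 fell, with a median of −0.16 (camera adjusted p = 0.0289; also 5 lower when adjusted over the list alone), and the call was lost without wild type array 1 (median −0.05, camera adjusted p = 0.105). Saa3 had a log2 difference of −0.21 (SE 0.11, adjusted p = 0.215). Of 23 measured cell cycle genes 9 fell, with a median of −0.33 (camera adjusted p = 3.86e-06; 12 lower when adjusted over the list alone). Mcm2, Mcm6 and Mcm4, of the replicative helicase, changed by −0.78, −0.73 and −0.62, and Rrm1, a ribonucleotide reductase subunit gene, by −0.45. With an estimated correlation both lists had an adjusted p = 0.552. The cell cycle list lost its call with the lymphocyte covariate (median −0.18, camera adjusted p = 0.115), as did the inflammatory list (−0.13, 0.141), and without transgenic array 2 the adjusted p was 0.0522 for Icam1 and 0.0526 for Mcm2. In the 6 fits with 1 array left out, Tnf and Mcm4 lost their calls in 3, Ccl5, Mcm6 and Rrm1 in 2, and Icam1, Vcam1, Cxcl13 and Mcm2 in 1.

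Macrophage genes went both ways. Of 27 measured members 2 rose and 3 fell, and the list did not pass (median 0.10, camera adjusted p = 0.671; 5 higher and 5 lower when adjusted over the list alone). Aif1 changed by −0.59, Lyz1, a lysozyme gene, fell 1.44-fold and Timd4 fell 1.83-fold (log2 −0.87, SE 0.20, adjusted p = 0.0285). Gpnmb rose 1.48-fold, and Fcgr3, an Fc receptor gene named after its value was seen, rose 1.33-fold. Of 6 single exclusions, Lyz1 and Fcgr3 lost their calls in 4, and Aif1, Timd4 and Gpnmb in 3. Adgre1, which encodes the macrophage marker F4/80, had a log2 difference of 0.46 that did not pass (SE 0.15, adjusted p = 0.0746).

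No list of respiratory chain or mitochondrial metabolism genes passed. In limma 0 of 37 measured complex I genes passed and 1 had an unadjusted p under 0.05, with a median of −0.03 (camera adjusted p = 0.816) that was 0.01 after centring each array and 0.03 with array weights. Likewise 0 of 33 measured genes of complexes II to V passed, 1 at an unadjusted p under 0.05 (median 0.03, camera adjusted p = 0.816), and 0 of 17 measured genes of the tricarboxylic acid cycle, 4 at an unadjusted p under 0.05 (median 0.02, camera adjusted p = 0.816). Adjusted over the list alone, each of these 3 lists again had 0. Of 29 measured fatty acid oxidation genes, Cpt1b and Pdk4 fell by 0.57 and 0.64 on the log2 scale and Hadh rose by 0.50, and the list did not pass (median 0.01, mean −0.01, camera adjusted p = 0.962; also 1 higher and 2 lower when adjusted over the list alone). Across the 6 fits that each leave out 1 array, Pdk4 and Hadh lost their calls in 5 and Cpt1b in 2. Cpt1a read 55.5 ± 1.9 and 60.4 ± 3.67, close to background.

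Skeletal muscle genes were high on a single wild type array. Their mean log2 deviation was 2.41 on wild type array 2 and between −0.91 and −0.15 on the other 5 arrays. The list had a median of −0.88 over 18 measured members (camera adjusted p = 0.0319; adjusted p = 0.812 with an estimated correlation), although 0 members passed in limma and 0 had an unadjusted p under 0.05, and the median was 0.07 without wild type array 2. The call ended with the filter on all 6 arrays (camera adjusted p = 0.0659) and without transgenic array 3 (0.107). Tnni2, a fast muscle troponin gene, read 938 ± 1312 (SD, n = 3) in wild type tissue and 163 ± 77.4 in transgenic tissue.

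**Figure D3:**
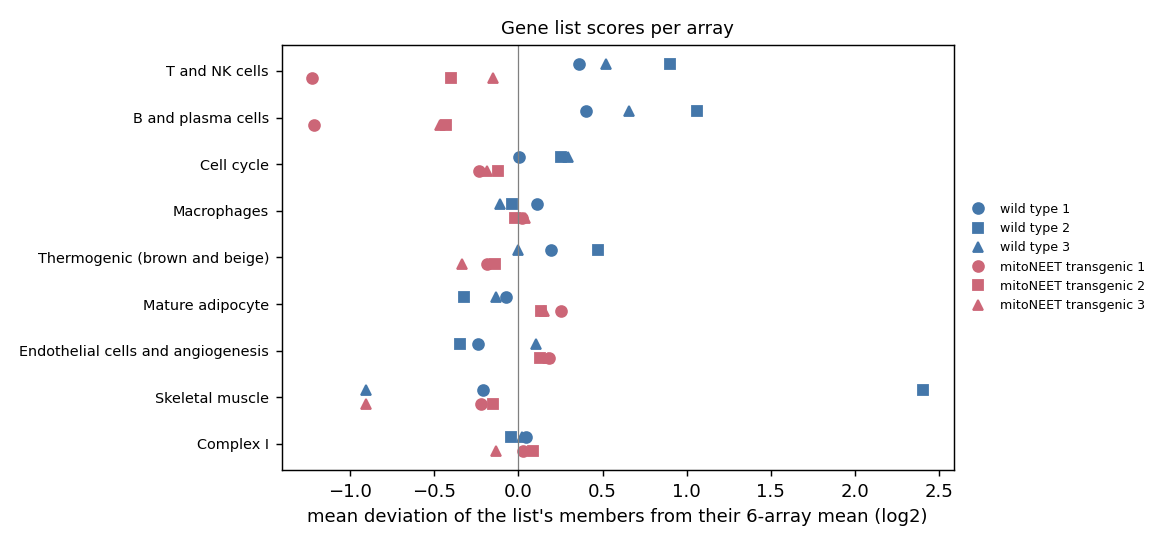
Mean log2 deviation of the members of 9 gene lists from their 6-array means, on each wild type array (blue) and mitoNEET transgenic array (red). Scores of T and NK cells, B and plasma cells and thermogenic genes were lower on all 3 transgenic arrays, adipocyte and endothelial scores were higher on all 3, and wild type array 2 stood apart in skeletal muscle genes at 2.41.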

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

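Alternatives added after the data were seen were background subtraction, centring, the lymphocyte covariate and the joint exclusion of wild type array 2 and transgenic array 1. Not run were neqc background correction, neqc with median centring and chip as a block, since scanner columns could not be assigned; the deposited values became the basis of the analysis, and detection filters were replaced by intensity thresholds. With each array left out in turn the count of features past the threshold ran from 0 to 2147 (0 to 997 higher, 0 to 1303 lower), lists past it from 9 to 14 and the Cisd1 log2 difference from 0.14 to 0.35. Fewer arrays give each such fit less power. Beyond single exclusions, 1311 values of named genes kept direction and side of the threshold, 344 were no longer past it, 5 newly passed and 21 reversed; for lists these were 388, 43, 5 and 19, leaving aside separate probes and the robust prior, which do not enter the list test. Lists that newly passed were lipolysis with the offset (camera adjusted p = 0.0469), no filter (0.00921), the stricter filter (0.0368) and the replicate block (0.0473), and epithelium with the stricter filter (0.0368). In single exclusions 387 values of named genes were no longer past the threshold, more than the 384 that kept direction and side, 3 newly passed and 6 reversed; for lists these were 6, 186, 6 and 12 in that order, the 6 that newly passed being lipolysis in 2 fits and lipogenesis, interferon, mitochondrial ribosome and epithelium in 1 each.

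Array weights gave 1247 higher features, an adjusted p under 0.10 gave 3450 (1591 higher, 1859 lower), and requiring 1.5-fold gave 909 (193 higher, 716 lower). Background subtraction gave 345 (85 higher, 260 lower) and 7 lists, ending the calls of iron, oxidative stress, fatty acid uptake, inflammatory and skeletal muscle genes. The filter on all 6 arrays ended those of iron (camera adjusted p = 0.081), oxidative stress (0.0505), fatty acid uptake (0.052) and skeletal muscle (0.0659). Without wild type 2 and transgenic 1 there were 317 (21 higher, 296 lower), and the calls of iron, oxidative stress and fatty acid uptake ended. Camera with estimated correlation and fry each gave 0 lists, 1 and 12 of them at an unadjusted p under 0.05. The lymphocyte covariate gave 0 features in limma (0 higher, 0 lower; 815 at an unadjusted p under 0.05) and 1 list, the thermogenic list (median −0.22, camera adjusted p = 0.0061). This covariate is built from T and B cell genes and follows genotype (correlation −0.88 over the 6 arrays), which widens standard errors (variance inflation 4.61); it takes out the change of T and B cell genes themselves by construction.

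Under that covariate Cisd1 reversed to −0.00318, as did Atp2a1 (0.40), Cox6a2 (0.51), Bcl11b (0.39), Bcl6 (0.041), Ccl19 (0.85), Ccl21c (0.97), Cd27 (0.45), Cd3d (0.56), Cd6 (0.30), Cpt1a (−0.071), Eno3 (0.29), Fabp5 (−0.028), Glycam1 (0.29), Hfe (−0.063), Irf1 (0.051) and Kdr (−0.17). List medians that reversed were complexes II to V (−0.077), mitochondrial ribosome (−0.083), iron (−0.015), oxidative stress (−0.027), cholesterol synthesis (−0.12), extracellular matrix (−0.10), macrophages (−0.049), interferon (0.037), T and NK cells (0.16), granulocytes (−0.12), skeletal muscle (0.48), circadian clock (−0.11) and heat shock (−0.11). Elsewhere Kdr reversed with array weights (−0.034) and without both arrays (−0.053), Prdm16 with centring (0.023), complex I with array weights (0.025) and centring (0.0062), progenitors with centring (0.0036), nerve genes with the filter on all 6 arrays (−0.0052), and without both arrays Atp2a1 (0.11), the tricarboxylic acid cycle (−0.0053) and skeletal muscle (0.017). Apart from muscle genes, high on wild type array 2 alone, and T and B cell genes under the covariate, the cause was not tested.

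Single exclusions turned the sign of several values: Atp2a1 ran from −2.51 to 0.36, Kdr from −0.014 to 0.12, Prdm16 from −0.084 to 0.075, complex I from −0.065 to 0.047, the tricarboxylic acid cycle from −0.021 to 0.044, fatty acid oxidation from −0.030 to 0.072, cholesterol synthesis from −0.012 to 0.14, extracellular matrix from −0.054 to 0.14, granulocytes from −0.041 to 0.30, progenitors from −0.14 to 0.098 and skeletal muscle from −1.37 to 0.066. With a replicate block the count was 2391. The samples share only a number: deviations of same-numbered arrays correlated at 0.41, 0.22 and −0.03, and not every sample correlated best with its own number. Signal over background limits what is seen at probes near background, among them those of the key genes Kdr, Cpt1a and Cd36.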

Other observations

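Tests written only after the result was seen were those on macrophage genes, on muscle RNA over the whole thermogenic list, on brown-like adipocytes and on adipocyte genes with the covariate; those on lymph node genes and on other splits of the arrays were written before. Insulin signalling genes included 4 rises among 18 measured members and no fall: Cav1, the caveolin gene, rose by 0.56 (SE 0.09, limma adjusted p = 0.0145), Slc2a4 by 0.55, Gys1 by 0.50 and Akt2 by 0.70, while the list did not pass (median 0.09, camera adjusted p = 0.328; also 4 when adjusted over the list alone). Among 20 measured immediate early genes Egr3 fell by 1.32, Klf2 by 0.70, Egr2 by 0.69 and Junb by 0.56 on the log2 scale, and Ccn1, named after its value was seen, rose by 0.50 (list median −0.07, camera adjusted p = 0.326; also 4 lower and 1 higher when adjusted over the list alone). Of 15 measured clock genes, Rora rose by 0.49 and Dbp by 0.38 (median 0.12, camera adjusted p = 0.328; also 2 when adjusted over the list alone). Fads1, a desaturase gene, rose by 0.66 and Pnpla3 by 0.56, while the elongase gene Elovl6 fell by 0.61, among 19 lipogenesis genes (median 0.20, camera adjusted p = 0.144; 4 higher and 1 lower when adjusted over the list alone). Nsdhl and Mvk, of cholesterol synthesis, rose by 0.59 and 0.53 among 15 measured (median 0.09, camera adjusted p = 0.279; 2 higher and 1 lower when adjusted over the list alone).

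In the extracellular matrix list of 44 measured genes, Ccn2 rose by 1.08, Nid2 by 0.43 and Timp3 by 0.33, Tgfb1 fell by 0.43, and Sparc, named afterwards, rose by 0.30 (median 0.07, camera adjusted p = 0.553; 5 higher and 1 lower when adjusted over the list alone). Among 23 hypoxia genes Vegfa rose while the phosphofructokinase genes Pfkp and Pfkl fell by 0.53 and 0.33 (median 0.06, camera adjusted p = 0.971; also 1 higher and 2 lower when adjusted over the list alone). Among 24 progenitor and fibroblast genes Dpp4 fell by 0.92, with Thy1 and Icam1, and Twist2 and Ebf1, the latter named afterwards, rose by 0.52 and 0.33 (median −0.03, camera adjusted p = 0.831; also 2 higher and 3 lower when adjusted over the list alone). Of 14 pericyte and smooth muscle genes Mcam rose by 0.57 and Des fell by 0.73 (median 0.21, camera adjusted p = 0.137), and of 9 nerve genes Pmp22 and Scn7a rose by 0.49 and 0.48 while Mbp fell by 0.46 and Egr2 fell as above (median 0.11, camera adjusted p = 0.891). Trp63, an epithelial transcription factor gene, rose 2.08-fold and Trf rose among 7 measured epithelial genes (median 0.17, camera adjusted p = 0.0766). Mrpl11 and Mrpl48 rose by 0.39 and 0.37 among 71 mitochondrial ribosome genes (median 0.06, camera adjusted p = 0.15, with 0 higher when adjusted over the list alone). Other lists that did not pass were lipolysis (median 0.22, camera adjusted p = 0.0555, with Plin1 higher by 0.54, and passing in some alternatives), interferon response (−0.11, 0.0909, with Irf1 lower at −0.53), heat shock and unfolded proteins (0.07, 0.452, with Xbp1 and Asns higher), mitochondrial dynamics (0.07, 0.403), granulocytes (0.15, 0.615) and blood (0.05, 0.661). Adjusted over the list alone, lipolysis had 4 higher, interferon response 0 lower and heat shock 1 higher. Of 6 single exclusions, Cav1, Thy1, Icam1, Trp63 and Hoxa9 (given next) lost their calls in 1 and Egr3 in 2, and the other genes called in these paragraphs in 3 to 6. Mesothelial genes, with 2 measured, were not tested. Hoxa9, a positional homeobox gene noticed while the values were inspected, rose from 116 ± 26.4 to 241 ± 3.12 (log2 1.08, SE 0.15, limma adjusted p = 0.0145). Of the ways to split 6 arrays into 3 and 3 there are 10, too few for a share under 0.05; the real split gave 2001 features and the highest other gave 0, so that 1 split reached that count.

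T and B cell lists were lower in camera's test with a preset correlation, though not with an estimated correlation (adjusted p = 0.552 for both) or with fry (0.095 and 0.0779), and their 37 measured members had a median log2 change of −1.37, with 29 lower past the threshold. Wild type pieces that included more lymph node are a candidate explanation. Fewer leukocytes of every kind would lower macrophage genes as well, but their median was 0.10 (bootstrap interval −0.08 to 0.31). With 1 array left out that median ran from 0.07 to 0.24, so macrophage genes did not fall as a set. The test was written after this median had been seen. It did not allow for dilution of wild type RNA, raised below for adipocyte genes, and the median reversed under the lymphocyte covariate. For these reasons the test cannot decide whether leukocytes of every kind were fewer. The bootstrap intervals here, and those given below for lymph node and thermogenic genes, resample the genes of a list. They treat genes as independent and leave out variation between arrays. Lymph node structure genes were written down beforehand, without Glycam1, Ccl19, Ccl21 and Cxcl13 because those had been seen. Their median was −0.24 (interval −0.68 to 0.09). A median that low came up in 0.12% of 10000 random lists matched for intensity. Those lists treat genes as independent, so this share is not a p-value for genes that move together. Of 9 measured genes 2 passed, Chst4, at least 1.37-fold lower over all arrays, and Bcl6 (log2 −0.88). Both are named afterwards, and their calls were lost in 5 and 2 of 6 single exclusions. Chst4 changed by −0.82 without wild type array 1. The −0.33 without wild type array 3 is of another Chst4 probe, since each fit chose the probe of highest mean again. The lost calls of Chst4 may therefore reflect a change of probe as well as the array left out. The bound set beforehand against lymph node, a median above −0.25, was met only within the spread; the rule that the interval must clear the bound was chosen, and Siglec1 taken off the list, after values were seen. Most of these genes lie near background, so more node in wild type pieces and a change in resident lymphocytes with genotype cannot be told apart.

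Ucp1, Fabp3, Acot11, Cox7a1, Cpt1b and Letmd1 were lower in transgenic tissue. The thermogenic list was lower in camera's test with a preset correlation. It did not pass with an estimated correlation (adjusted p = 0.552) or with fry (0.0779). Muscle RNA on wild type array 2 is argued against as the whole cause: without that array the muscle list went from −0.88 to 0.07, while the thermogenic list kept its call (camera adjusted p = 0.00124, preset correlation) with a median of −0.21 (interval −0.50 to −0.02) against −0.28, and Ucp1 was −1.23 (SE 0.15, limma adjusted p = 0.0396). The bound used, an interval below 0, was set after the value was seen in place of −0.5, which was not met, and muscle stays open for Atp2a1 and Cox6a2, members named afterwards that did not pass and went from −1.29 to 0.36 and from −1.21 to −0.22. The test for fewer brown-like adipocytes assumed that all 22 measured members fall, which need not hold for Atp2a1 and Cox6a2. The median of the 22 members was −0.28 (interval −0.57 to −0.09). That interval includes both bounds set for this test, so fewer brown-like adipocytes stay open as an explanation. An effect of the transgene within adipocytes may also lower these genes and was not tested.

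The adipocyte list, with a median of 0.31 and 8 of 23 measured members past the threshold, was higher in camera's test with a preset correlation, though not with an estimated correlation (adjusted p = 0.552) or with fry (0.0779). Dilution of wild type adipocyte RNA by lymph node RNA is a possible explanation. With the lymphocyte score as covariate the median of the limma changes was 0.057. A separate linear model took the median deviation of the list on each array, with the same covariate. Its genotype term had a confidence interval of −0.40 to 0.55. That interval covers both no change and the whole change, because the score follows genotype closely (variance inflation 4.61), so dilution and an effect of genotype cannot be told apart for these genes.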
